A study of Caenorhabditis elegans with 2 samples.

How the data were processed

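The 2 groups of whole worms (strain N2, age given as Day 1) were represented by 1 small RNA library each, enoxacin replicate 1 and vehicle replicate 1. Per the labels' protocols, TRIzol-extracted total RNA had integrity numbers over 9, small RNA was enriched from 10 µg per group, and libraries were made with a SOLiD kit. SOLiD sequences by ligation. The submitters state that worms came from 3 independent experiments, and whether these were pooled into each library is not given in the sources used here. The submitters' processing notes name Bowtie2 (a read aligner), bedtools (which counts reads over intervals) and the genome build ce10. Versions, roles, filters and the handling of strand and of reads with several matches are not given in the sources used here.

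The authors deposited 1 table of 375 mature miRNA loci (223 hairpins) with miRBase identifiers and positions. It holds a raw read count per locus and library. It also holds RPM values (reads scaled to the library total) that the authors obtained by dividing each count by 1 fixed total per library. These totals, recovered from the deposited count and RPM columns, were 10698845 for vehicle and 8787665 for enoxacin, so the table holds a small part of each library. The deposited table further gives the enoxacin to vehicle ratio of the RPM values and its log2, and both equalled the values computed here without a pseudocount where both counts were above 0. The column headed as control was assigned to the vehicle sample, the one described as control worms. The table's positions are taken as ce10 from the processing notes. The annotation at hand is of another build, WBcel235 (Ensembl), so it was used only by hairpin name to find overlapping genes, with no coordinates: 99 of 101 hairpin names matched.

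For each locus the ratio was (enoxacin count / enoxacin total) / (vehicle count / vehicle total), with an exact conditional binomial (Clopper-Pearson) interval at 95%. Log2 ratios used a pseudocount of 0.5 reads. Loci with at least 20 reads over both libraries (152) were compared. A locus was counted as higher or lower at a 1.5-fold log2 ratio with an interval excluding 1. These intervals, and the limit of 3 counts used where a library had no read, cover counting error only, since each group had 1 library. They treat reads as independent. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error. No p-value was computed. One read was worth 0.0935 RPM in vehicle and 0.114 RPM in enoxacin. The criterion was tested on simulated data: counts were drawn from the real means and totals for the 152 loci in 200 draws with 40 changed loci each. It called 80.2% of 2-fold and 98.4% of 4-fold changes and 1.55% of unchanged loci, and 95.9% of intervals covered the simulated ratio. The simulation holds counting error alone, so it says nothing of the spread between cultures.

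The 18 lists (lifespan and heterochronic miRNAs, mirtrons, 11 seed families and 4 tissues) were fixed before the data were examined, together with the alternatives and the naming rule. Each list took all arms and copies of its members. A family list thus also holds the less abundant (minor) arms, which need not share the family's seed. A list's median log2 ratio was placed among 10000 random lists of the same size, drawn for each member from the 30 nonmembers nearest in read count. The named miRNAs are both mir-34 arms, the 12 highest and 12 lowest ratios that passed the criterion, the 8 most abundant, and for each list all compared members or, if more than 4, the 4 most abundant. miR-49-5p, miR-55-3p and lsy-6 were named in addition after their values were seen. Alternatives were other scalings (median of ratios; TMM from edgeR 4.0.16; totals without the 3 most abundant miRNAs), the minimum (none or 100 reads), a pseudocount of 1, thresholds of 2 and 1.25, arms summed per hairpin, and for lists the major arm only or summed reads. Scaling by the sum of the miRNA table, with and without its 3 most abundant miRNAs, was added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3, were used.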

Results

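Small RNA was sequenced from whole Caenorhabditis elegans of the wild-type strain N2 that had received either enoxacin or its vehicle, with 1 library per group. Enoxacin is a fluoroquinolone antibiotic that is also known to bind the Dicer partner TRBP in mammalian cells and to promote microRNA (miRNA) processing there. The comparison of the 2 libraries addressed which mature miRNAs differ in abundance when worms receive the compound. The authors' library totals were 10698845 reads for vehicle and 8787665 reads for enoxacin. Levels are given in RPM, reads scaled to the library total. Mature miRNA loci took 400555 reads (3.74%) of the vehicle total and 332407 reads (3.78%) of the enoxacin total. Of the 375 mature miRNA loci, 257 had a read in at least 1 library, and 152 reached the minimum of 20 reads over both libraries used for comparison. With 1 library per group there was no replicate error, so no difference between the groups could be tested. Each ratio of enoxacin to vehicle is given with an exact 95% interval that covers counting error only. A miRNA was counted as higher or lower when its ratio passed 1.5-fold and this interval excluded a ratio of 1.

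The miRNA profile was dominated by the same few species in both libraries. miR-52-5p took 23.5% of miRNA reads in vehicle (95% exact binomial interval 23.4 to 23.7%) and 23.7% in enoxacin (23.5 to 23.8%). miR-66-5p took 18.7% in vehicle and 15.8% in enoxacin. The next were miR-36-3p, with 7.24% and 6.91%, and miR-80-3p, with 7.13% and 7.90%. miR-54-3p, miR-87-3p, miR-229-5p and miR-72-5p completed the 8 most abundant, each with between 2.25% and 3.92% of miRNA reads. miR-52-5p differed little between the libraries, with a ratio of 1.02 (1.01 to 1.03). miR-66-5p was slightly less abundant in enoxacin, with a ratio of 0.852 (0.843 to 0.862).

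The mir-34 hairpin, whose miRNA belongs to a conserved family linked to stress responses and ageing, showed an arm-specific difference. miR-34-5p had 900 reads (84.1 RPM) in vehicle and 37 reads (4.21 RPM) in enoxacin. Its level was thus 20-fold lower in enoxacin, a ratio of 0.0501 (0.0350 to 0.0695). miR-34-3p, from the other arm of the same hairpin, had 1055 reads in vehicle and 765 in enoxacin, a ratio of 0.883 (0.803 to 0.970). The 5p arm made up 46.0% of mir-34 reads in vehicle (43.8 to 48.3%) and 4.61% in enoxacin (3.27 to 6.30%). With both arms summed, mir-34 had a ratio of 0.499 (0.459 to 0.543). The miR-34-5p locus lies on chromosome X from 2969802 to 2969823 on the minus strand (ce10). In the WBcel235 annotation the mir-34 hairpin overlaps no other annotated gene.

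Most miRNAs did not pass the criterion. Of the 152 compared, 120 (78.9%) were neither higher nor lower by the criterion, 20 were higher in enoxacin and 12 were lower. The median ratio was 1.09, with quartiles of 0.884 and 1.35. Scaling by the median of ratios moved all log2 ratios down by 0.13, so modest ratios are best read against this median. A further 13 miRNAs passed 1.5-fold, 9 upward and 4 downward, but their counting intervals included 1. At any fold, the counting interval excluded 1 for 49 loci upward and 26 downward. The 20 higher loci came from 19 hairpins and the 12 lower loci from 11. The 20 include miR-5592-5p and miR-5592-3p, which overlap on opposite strands and hold the same counts (72 reads in vehicle and 102 in enoxacin), so both may count the same reads. With such pairs counted once, 19 loci from 18 hairpins were higher. Each of these 2 mature miRNAs has another copy, at the other hairpin named mir-5592, that was neither higher nor lower. That copy of miR-5592-5p had a ratio of 1.31 (0.957 to 1.78) and that of miR-5592-3p 1.36 (0.987 to 1.89). Copies of 1 mature miRNA share a sequence, so their reads cannot be told apart and the separate values of the copies are uncertain.

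**Figure D1:**
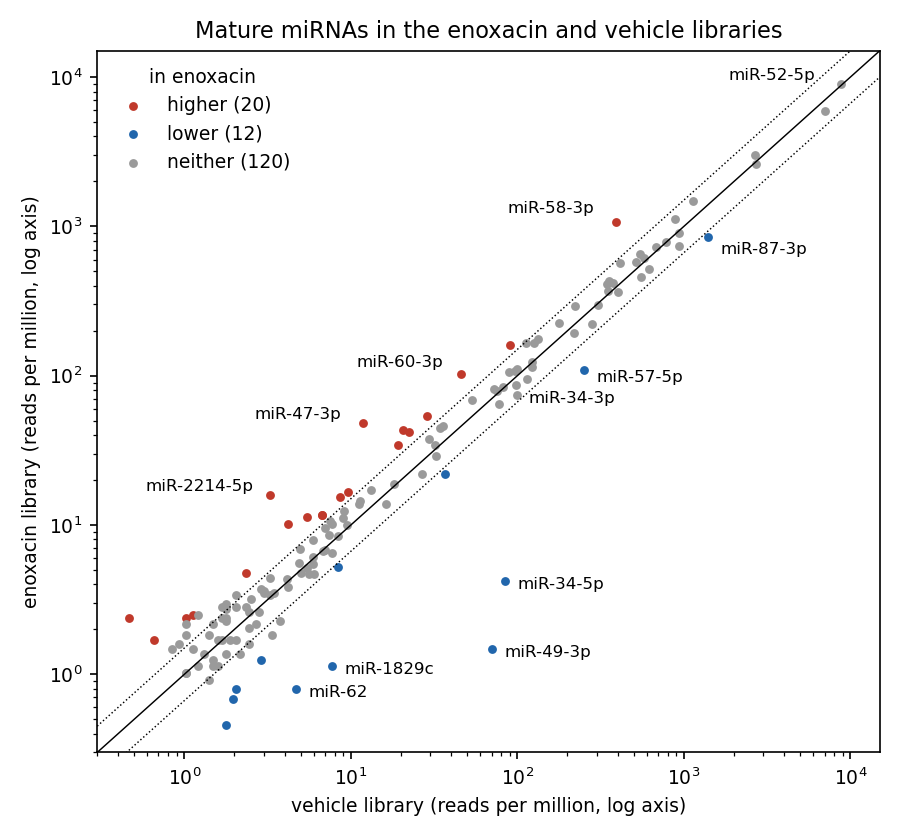
RPM values of the 152 mature miRNAs with at least 20 reads over both libraries, in the vehicle library (x axis, log scale) and the enoxacin library (y axis, log scale). Each point is 1 miRNA locus, the solid line marks equal levels and the dotted lines a 1.5-fold difference. Most points lie between the dotted lines, while miR-34-5p and miR-49-3p lie far below them.

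Among the miRNAs lower in enoxacin, the lowest ratio belonged to miR-49-3p, ahead of miR-34-5p. miR-49-3p (chromosome X, 9989284 to 9989305, plus strand, ce10) had 758 reads in vehicle and 13 in enoxacin, which was 47.9-fold lower (ratio 0.0209, 0.0111 to 0.0359). Its 5p arm had 1 read in each library, so the arms could not be compared. miR-1829c had 82 reads in vehicle and 10 in enoxacin (ratio 0.148, 0.0686 to 0.287), and its relative miR-1829b had 90 and 46 (0.622, 0.426 to 0.897). Both lie within introns of protein-coding genes in WBcel235, miR-1829c in piki-1 and miR-1829b in F20D1.3. Because the mir-1829 copies are closely related, reads could be divided between them by the mapping, and their separate values are uncertain. miR-62, which is released by splicing of an intron of ugt-50 and so bypasses Drosha, had 50 reads in vehicle and 7 in enoxacin (0.170, 0.0652 to 0.378).

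Both arms of mir-57, a hairpin known for its role in posterior cell fate, were lower in enoxacin. miR-57-5p had 2683 and 962 reads (0.437, 0.405 to 0.470), and miR-57-3p had 19 and 4 reads (0.256, 0.0634 to 0.771). In WBcel235 a non-coding RNA gene overlaps the hairpin on the opposite strand, as for 22 of the 99 hairpins matched by name, mir-87 and mir-60 among them. miR-87-3p was the most abundant miRNA to count as lower, with 1393 RPM in vehicle and 849 RPM in enoxacin (0.610, 0.593 to 0.627). The others were minor arms of abundant hairpins. miR-52-3p had a ratio of 0.601, miR-43-5p of 0.432, miR-38-5p of 0.387 and miR-53-3p of 0.348. Of these 4, only miR-52-3p had more than 31 reads in either library.

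Among the miRNAs higher in enoxacin, miR-58-3p was the most abundant. It belongs to the bantam-related mir-58/80 family, and it had 393 RPM in vehicle and 1073 RPM in enoxacin (ratio 2.73, 2.64 to 2.83). Its locus (chromosome IV, 3233311 to 3233332, plus strand, ce10) lies within an intron of Y67D8A.2 in WBcel235, where the non-coding RNA gene Y67D8A.6 also overlaps it. miR-47-3p had 127 reads in vehicle and 424 in enoxacin (4.06, 3.33 to 4.996). Its family member miR-46-3p, which is nearly identical in sequence, had 384 and 404 reads (1.28, 1.11 to 1.48). Both arms of mir-2214, within an intron of B0361.11, were higher: miR-2214-5p at a ratio of 4.84 (3.32 to 7.22) and miR-2214-3p at 2.08 (1.49 to 2.93). miR-60-3p, a miRNA known from the intestine, had 488 and 907 reads (2.26, 2.02 to 2.53). miR-238-3p, for which a role in lifespan is known, had 220 and 380 reads (2.10, 1.78 to 2.49). miR-59-3p had a ratio of 2.41 (1.66 to 3.53) and miR-229-3p of 2.05 (1.22 to 3.50).

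The remaining members of the 12 highest rested on few reads. miR-37-5p had 5 reads in vehicle and 21 in enoxacin (5.11, 1.88 to 17.4), while miR-37-3p, the abundant arm of that hairpin, had a ratio of 0.824. miR-90-5p, miR-84-3p and miR-61-5p had 7, 11 and 12 reads in vehicle against 15, 21 and 22 in enoxacin. Their ratios were 2.61, 2.32 and 2.23, with lower bounds of 1.00, 1.07 and 1.06. None of these 3 counted as higher under median-of-ratios or TMM scaling.

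**Figure D2:**
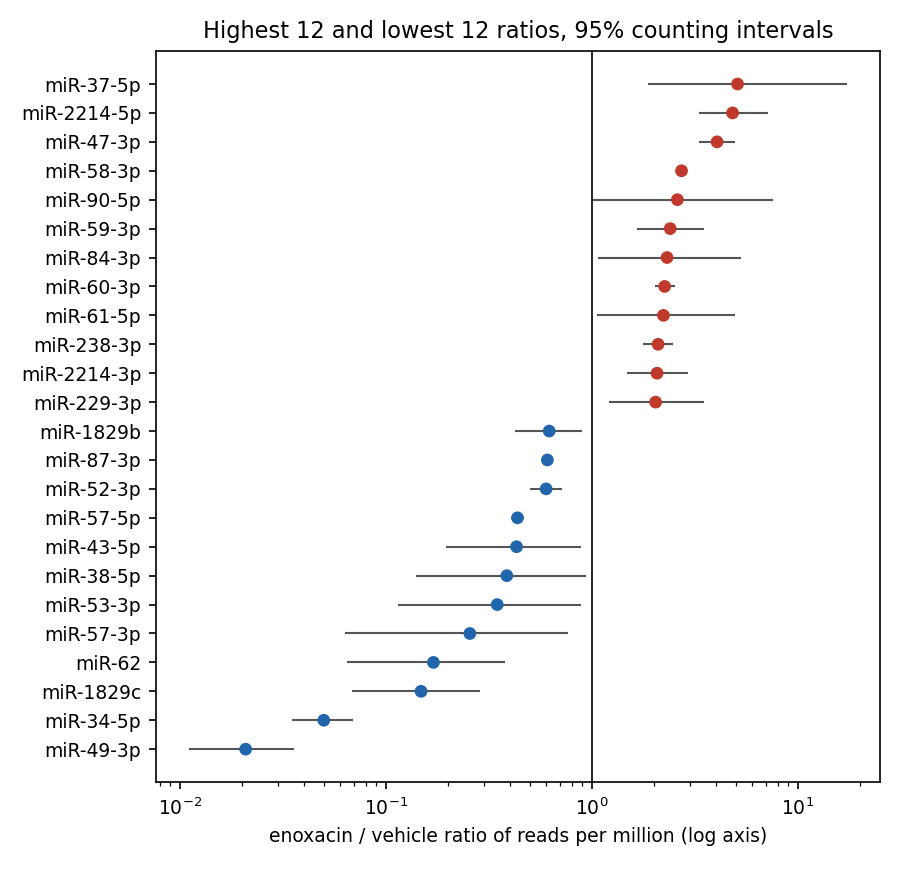
Ratio of enoxacin to vehicle in RPM (x axis, log scale) for the 12 miRNAs with the highest and the 12 with the lowest ratios among those that passed the criterion. Points are the ratios of 1 library to the other and bars their exact 95% counting intervals, and the interval of miR-49-3p lies below that of every miRNA shown except miR-34-5p, whose interval starts at 0.0350.

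Lists of miRNAs fixed in advance were then compared. Of the lifespan list, 19 of 26 loci were compared, 2 were higher (miR-58-3p and miR-238-3p), 1 was lower (miR-34-5p) and 16 were neither. Its median ratio of 1.18 lay at percentile 75.6 of random lists matched on abundance. miR-71-5p, which is known to promote lifespan, had 8404 and 6954 reads (1.01, 0.976 to 1.04). lin-4-5p had a ratio of 1.18 (1.13 to 1.24) and miR-80-3p one of 1.12 (1.10 to 1.14). The heterochronic list, which times larval development, had 1 higher locus of 9 compared, the minor arm miR-84-3p, and none lower. Within it, let-7-5p had a ratio of 1.48 (1.37 to 1.60), just short of the criterion, while miR-84-5p was at 1.06 and miR-48-5p at 0.885 (0.831 to 0.942). The let-7 family had a median ratio of 1.08, which did not keep its side of 1 under every alternative, with miR-241-5p at 0.891. The 3 compared loci of the lin-4 family were neither higher nor lower, with miR-237-5p at 1.29 and lin-4-3p at 0.920.

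The mir-35 family, which is abundant in embryos and required for their development, had 14 loci compared. One was higher (the minor arm miR-37-5p), 1 was lower (the minor arm miR-38-5p) and 12 were neither. Its median ratio was 0.955 and its summed reads had a ratio of 0.945 (0.934 to 0.957). miR-36-3p had a ratio of 0.964, miR-35-3p of 0.795, miR-37-3p of 0.824 and miR-39-3p of 1.07. The mir-51 family, the most abundant one, had a median ratio of 1.07, which fell below 1 under median-of-ratios and TMM scaling. Its locus miR-55-3p was higher (1.85, 1.60 to 2.15) and miR-52-3p and miR-53-3p were lower. Within it, miR-54-3p was at 1.31, miR-56-3p at 1.20 and miR-53-5p at 1.12. In the mir-58/80 family miR-58-3p alone of 7 loci was higher, whereas miR-80-3p, miR-82-3p and miR-81-3p had ratios of 1.12, 1.07 and 0.976, and the median was 1.26. The mir-64 family, whose hairpins lie within introns of gcn-1 in WBcel235, had 1 higher locus of 7 (the minor arm miR-229-3p). Its median ratio was 1.254, with miR-64-5p and miR-65-5p both at 1.31 and miR-229-5p at 1.254, but its summed reads had a ratio of 0.916, on the other side of 1, since most of them were miR-66-5p.

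The mir-2/43 family was the list whose median lay outside the central 95% of random lists, at percentile 2.41 with a median ratio of 0.805. miR-2-3p was at 0.837 (0.806 to 0.869), miR-250-3p at 0.838 (0.766 to 0.916), miR-43-3p at 0.740 (0.671 to 0.817) and miR-43-5p at 0.432, the 1 locus of 6 that counted as lower. Among 18 lists, about 1 is outside that range by chance. This family was inside it under 4 of 10 alternatives, such as a minimum of 100 reads or the major arm only. With the major arm only its median log2 ratio was -0.256, against -0.313 in the main setting, which includes minor arms. In the mir-44/45/61 family, the minor arm miR-61-5p was higher, and miR-44-3p, miR-45-3p and miR-61-3p were at 1.05, 1.01 and 1.27. The family median of 1.03 did not keep its side of 1 under every alternative. miR-44 and miR-45 share a mature sequence, so their reads cannot be told apart. The mir-46/47 family had a median ratio of 1.35, with miR-47-5p at 1.42 and miR-46-5p at 1.05 beside the 3p arms given above. Its summed reads had a ratio of 1.84 (1.66 to 2.04). In the mir-72/74 family miR-74-3p was higher (1.89, 1.60 to 2.23) and miR-72-5p, miR-72-3p and miR-73-3p were at 0.963, 1.30 and 1.11. Its median ratio was 1.20 and the ratio of its summed reads was 0.997. The family of mir-238 and mir-239 had a median of 1.24, with miR-239a-5p at 1.24 and miR-239a-3p at 1.05. Of the mirtrons, miR-62 alone reached the minimum.

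Of the tissue-associated miRNAs compared, miR-60-3p alone passed the criterion. The muscle miRNA miR-1-3p had 4314 and 3197 reads (0.902, 0.862 to 0.945), and miR-1-5p had a ratio of 1.04 (0.712 to 1.53). The neuronal miR-124-3p had 174 and 121 reads (0.847, 0.666 to 1.07), and lsy-6 had no read in either library, which allows up to 0.280 RPM in vehicle and 0.341 RPM in enoxacin. miR-228-5p, known from epidermis and glia, had 1309 and 1082 reads (1.01, 0.928 to 1.09). The minor intestinal arm miR-60-5p had only 17 and 10 reads (0.716, 0.293 to 1.66), and the median of the 2 mir-60 arms was 1.29.

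**Figure D3:**
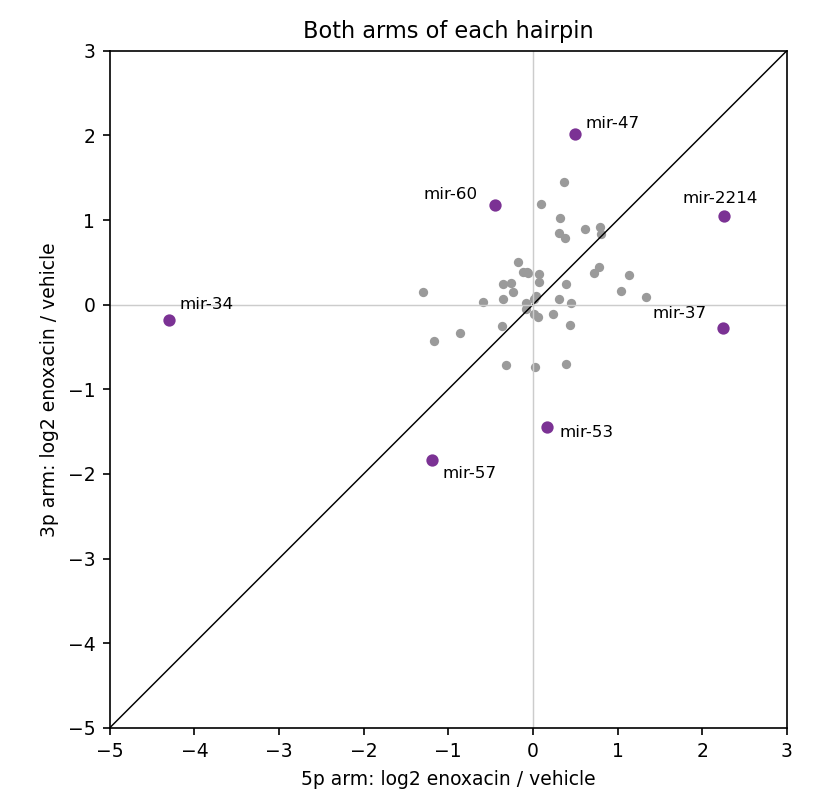
Log2 ratio of enoxacin to vehicle of the 5p arm (x axis) and the 3p arm (y axis) for the 49 hairpins with both arms at 20 reads or more. Each point is 1 hairpin and the diagonal marks equal change of both arms. mir-34 lies farthest from the diagonal, with a 5p minus 3p difference of -4.12, and mir-57 and mir-2214 are the hairpins with both arms past the criterion in 1 direction.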

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

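With 1 library per group there is no replicate to leave out, and every difference is between 2 libraries. The 20 higher and 12 lower loci became 12 higher at a threshold of 2, 35 higher at the lower alternative threshold, and 13 higher and 7 lower with arms summed per hairpin. With a minimum of 100 reads 6 loci were lower, since fewer loci were compared. The other settings gave 15 to 23 higher and 9 to 15 lower loci. Median-of-ratios and TMM scaling, which moved all log2 ratios by -0.13 and -0.14, gave 17 higher and 14 lower. miR-34-5p counted as lower under every scaling and pseudocount run, with log2 ratios from -4.44 to -4.28, and miR-34-3p stayed outside the criterion, at -0.18 in the main setting and -0.32 with TMM. For the miRNAs named by the rule fixed in advance, other than the mir-34 arms, 396 values were computed under the scalings and the pseudocount of 1: 77 had a changed call or lay outside their counting interval, no call changed direction, and 8 calls were lost, those of miR-90-5p, miR-84-3p and miR-61-5p. At a threshold of 2, calls were also lost for 4 of them, miR-74-3p, miR-1829b, miR-87-3p and miR-52-3p, and for miR-55-3p and miR-85-3p. The number of lists outside the central 95% of random lists was 1 in the main setting, 2 with no minimum and 0 with a minimum of 100. The list outside was the mir-2/43 family under all scalings and a pseudocount of 1, the mir-46/47 family with the major arm only, the lifespan list with summed reads, and the let-7 and mir-35 families with no minimum. Of 179 list values under alternatives, 28 lay outside their counting interval, and the values of 8 lists turned to the other side of a ratio of 1 under at least 1 alternative. These were the let-7, mir-35, mir-44/45/61, mir-51, mir-64 and mir-72/74 families, the neuron list, and the list for epidermis and glia. Those of the mir-64 and mir-72/74 families turned only as the ratio of summed reads. The median log2 ratio of the let-7 family was 0.11 in the main setting, -0.17 with a minimum of 100 reads and -0.03 with TMM. miR-52-5p moved from 0.02 to -0.10 under median-of-ratios scaling. The median log2 ratio of the mir-46/47 family was 0.43 in the main setting and 1.19 with the major arm only, and the log2 ratio of its summed reads was 0.88. The cause of these moves was not tested. Depth limits the loci under 20 reads (223 of 375) and the minor arms, whose intervals often span several-fold.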

Other observations

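Of 49 hairpins with both arms compared, 22 had at least 1 arm past the criterion. In 2 both arms were past it in 1 direction (mir-57 and mir-2214), and in 0 they were in opposite directions. Over all 152 loci 20 were higher and 12 lower, and many minor arms had few reads. These counts thus do not show whether the arms of a hairpin shift apart. miR-85-3p, with 961 and 1413 reads (ratio 1.79, 1.65 to 1.95), was the second most abundant miRNA to count as higher and was picked out after its values were seen. miR-83-3p, which shares its seed with miR-49-3p, had 366 and 393 reads (1.31, 1.13 to 1.51), against the 47.9-fold lower miR-49-3p. It and the miR-1829a, miR-5592 and miR-356 loci below were likewise chosen after their values were seen.

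The tests of the 5p arms, of the 22-nt class and of the minor arms were set out before their results were seen. Those of the mir-34 hairpin, the near-identical copies, strand, families and clusters were chosen only after the results were seen.

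miR-34-5p was 20-fold lower in enoxacin while miR-34-3p was near equal. Less of the whole hairpin would lower both arms, and miR-34-3p kept a ratio of 0.883 with a lower bound of 0.803. A shift of all 5p arms against 3p arms is argued against by the other 48 hairpins, whose median 5p minus 3p log2 difference was -0.11 (bootstrap interval -0.40 to 0.15), with -1.63 for mir-60 as the lowest. Loss of miRNAs of 22 nt is argued against by the other 59 of that length, whose median log2 ratio was 0.10 (0.02 to 0.26). Open are an effect of enoxacin on this strand, a difference between the cultures apart from enoxacin, and a sequence-specific loss in preparing or mapping 1 library. These cannot be told apart with 1 library per group.

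Across hairpins the minor arm, taken as the one with fewer reads over both libraries, tended to be lower than the major arm in enoxacin. The median minor minus major log2 difference was -0.28 (bootstrap interval over hairpins -0.46 to -0.10), with the minor arm lower in 35 of 49 hairpins, and it was -0.28 without mir-34. The choice of arm can itself favour this result. Where the arms are near equal in vehicle, the one higher in enoxacin becomes the major arm. In vehicle alone, mir-2214 had 35 reads on 5p and 58 on 3p, and mir-240 had 96 and 92. Their minor arms would then be the other ones, and their differences of -1.21 and -0.53 would change sign. Whether the tendency holds with arms chosen by vehicle reads was not tested. As a test of low counts, 21 major arms with 29 to 103 reads were taken, nearly all from hairpins outside the 49. Their median log2 ratio was 0.28 (0.11 to 0.42), against 0.03 (-0.12 to 0.31) for the minor arms. The interval of the major arms lay above the median of the minor arms. The 2 intervals overlap and the arms are not paired, so low counts stay open as a cause. A hypothesis is that fewer minor strands were kept relative to major ones in the enoxacin library, and a difference in size selection or ligation between the libraries may give the same and was not tested. The 49 include 2 hairpins named mir-5592 on opposite strands, which may share reads. Hairpins are not replicates, and another pair of libraries would be needed to test either.

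Some values could depend on how reads were assigned. If reads of miR-46-3p given to miR-47-3p were the whole cause, their sum would be near the typical ratio, but it was 1.97 (1.76 to 2.21). If reads of miR-1829b and miR-1829c given to miR-1829a were the whole cause, the sum of the copies would be too, but it was 0.463 (0.345 to 0.615). A part played by such division, or reads left out for matching several places, stays open. Of 3 pairs of miRNAs that overlap by 15 nt or more on opposite strands, 2 held the same count in both libraries: miR-5592-5p and miR-5592-3p with 72 reads in vehicle and 102 in enoxacin, and miR-356a and miR-356b-3p with 5 and 4. Counting without regard to strand would give this, but the equal counts themselves prompted the test, so it stays open. In that case reads from RNAs opposite mir-57, mir-60 or mir-87 would be included in their values. Such RNAs lie opposite 22 of the 99 matched hairpins, let-7, lin-4, mir-1, mir-52, mir-71, mir-80, mir-85 and mir-124 among them.

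Members of a seed family and neighbours in a genomic cluster were compared for like shifts. The median absolute log2 difference between members of a family was 0.33 over 95 pairs, at percentile 1.53 when ratios were shuffled over all hairpins but at percentile 17.5 when shuffled within classes of like abundance. For hairpins within 10 kb on 1 strand it was 0.30 over 47 pairs, at percentiles 3.81 and 19.5. The second shuffle was added after the first was seen. The family value passed the bound of 2.5 only in the first shuffle and the cluster value in neither, so a shared shift of families or clusters was not shown.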
